A study of Homo sapiens with 4 samples.

How the data were processed

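RNA was measured by sequencing in 4 libraries of HT1080, an established human fibrosarcoma cell line, all labelled with a knockout of KDAC6. KDAC6 is the lysine deacetylase encoded by HDAC6. Per the labels' protocols, cells were grown in MEM with fetal bovine serum, pelleted, frozen and shipped on dry ice before total RNA was extracted. Ribosomal RNA was then depleted with the Ribo-Zero Plus kit and paired-end libraries were made, per the same protocols. The labels place all 4 libraries in 1 group, numbered 1 to 4, and no control libraries were analysed here. How the knockout was made, which part of HDAC6 was altered, and whether the 4 replicates came from separate cultures are not given in the sources used here. No p-value here therefore measures replication across cultures, and the spread between these samples may be technical. Of the tests described below, the variance test sets a gene's spread between these samples against that of other genes. The Fisher and list permutation p-values rest on genes, not libraries.

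The values analysed are estimated counts per gene (expected counts), deposited by the authors as 1 table of 60675 Ensembl genes. Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2 2.5.4, RSEM 1.3.3 and DESeq2 1.46.0 were used with the GRCh38 genome build. The role and order of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. Between 10.6% and 12.7% of the deposited expected counts per library were not whole numbers, so reads shared between genes had been divided among them. Of 15544 genes with an estimate of at least 10 in every library, 43.5% had an estimate that was not whole in at least 1 library. Values of near-identical gene copies depend on that division and are uncertain. Without a stated strand setting, reads of an antisense gene and of the gene it overlaps cannot be told apart. The estimates were rounded to whole numbers before any test. The table held no value columns other than those of the 4 libraries.

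Gene positions, types, transcript lengths and GC content came from GENCODE release 29 on GRCh38, which held 57055 of the 60675 gene identifiers. Genes without an entry held at most 0.057% of a library's counts. Gene symbols are those of the deposited table, except RN7SL2, which is Metazoa_SRP there, and 56558 identifiers were also matched to current symbols. Positions of ribosomal RNA genes came from the RefSeq annotation of GRCh38. There were 27 gene lists, with 371 distinct genes, of which 365 were matched. The 6 unmatched genes were 4 nuclear ribosomal RNA genes and the histone genes H3C2 and H3C3, which are not analysed here.

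Library totals were 43815270, 48903021, 42589262 and 34403387 counts in libraries 1 to 4. A count of 0 allows up to 3 counts, or 0.0700, 0.0601, 0.0713 and 0.0860 CPM (TMM-scaled counts scaled to a common library total) in libraries 1 to 4. These floors, and the exact 95% Poisson intervals given for HDAC6, cover counting error only, since reads without molecular identifiers are not independent molecules.

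CPM values were computed from the deposited estimated counts with edgeR 4.0.16 in R 4.3.3, scaled by TMM factors of 0.978, 1.02, 0.988 and 1.01. Log2 values are log2(CPM + 0.5). A gene was called detected at 1 CPM or more in every library. For tests across genes, 17176 genes with at least 10 counts in at least 2 libraries were kept. Genes that vary between libraries were found with edgeR's quasi-likelihood fit of a single mean. The ratio of each gene's quasi-dispersion to the fitted prior was set against an F distribution in an upper-tail test with 3 residual degrees of freedom. Benjamini-Hochberg adjustment was over all genes tested, with a threshold of 0.05. This test departs from the plan. The plan gave each gene its own prior degrees of freedom from the robust fit, and in that form 0 genes passed (edgeR, 705 at an unadjusted p under 0.05, smallest adjusted p = 0.99). The form used gives every gene the common value of that fit, 25.1, and was chosen after the counts under both forms, 0 and 172, had been seen. The reason is that the robust fit lowers the value for the genes that vary most, to as little as 0.200, so that no gene can stand out. The edgeR adjusted p-values for varying genes all come from the form chosen later, and the limma-voom alternative also used a common value.

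The spread of a gene list was the median over its members of the SD of log2 values across libraries, placed among 10000 random lists of the same size matched in 20 bins of expression. These two-sided permutation p-values were adjusted over the lists with at least 3 members tested. The other lysine deacetylases were compared with HDAC6 within each library by an exact two-sided sign-flip permutation test. Its 16 sign patterns cannot give a p below 0.125, so this comparison could not reach 0.05. Gene classes were compared by two-sided Fisher's exact tests against all genes tested. Libraries that stand apart were found with Dixon's gap ratio at its 95% critical value for 4 samples.

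The variance test was checked on counts simulated for the 17176 genes from their means, library sizes and fitted dispersion trend, with 200 genes of mean count 50 or more changed in 1 library. It recovered 87% of the 100 genes changed 2-fold and 100% of the 100 changed 4-fold. Of all calls, 1.06% were unchanged genes, and 0 genes were called when nothing was changed. Every unchanged gene was simulated exactly on the dispersion trend, and no reads were shared between genes. These rates therefore need not hold for the deposited counts. On the same simulated counts the planned form recovered 0% of the genes changed 2-fold and 0% of those changed 4-fold, and the fit without the robust prior, also set beforehand, recovered 75% and 100%. This simulation was run after the form had been chosen. In the list test, 6.2% of 500 random lists had a permutation p below 0.05 when nothing was changed, slightly more than 5%.

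The genes named were set by a rule fixed before the data were examined, as were the lists, most alternatives and the tests other than the form of the variance test. The rule takes HDAC6, every other lysine deacetylase, ATAT1, up to 4 members with the highest mean CPM of each list and up to 3 of each list of other cell types. It also takes the 10 genes with the highest mean CPM and the 10 with the smallest adjusted p for variance. Some genes that the rule takes are not used here. All other genes named, such as CDKN2A, NEAT1, CA9, SNORD3A and the varying mitochondrial mRNAs, were chosen after their values were seen. Genes of the sex chromosomes that could reveal a sex were not reported. The alternatives tried were other scaling, filters, pseudocounts, denominators, per-kilobase values with and without a pseudocount (the latter chosen after the data were seen), non-robust and limma-voom (limma 3.58.1) variance tests, DESeq2 1.42.0 dispersion outliers, and leaving out each replicate in turn. Tables were prepared in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.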

Results

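Gene expression was profiled in HT1080 cells labelled as KDAC6 knockout, in 4 libraries of rRNA-depleted total RNA. The study's title asks how loss of KDAC6, a mostly cytoplasmic deacetylase of α-tubulin and other proteins, affects gene expression. With 1 group and no control libraries analysed here, an effect of the knockout could not be tested, and the data describe the transcriptome of the labelled cells and its spread between replicates. Library totals ranged from 34403387 counts in library 4 to 48903021 in library 2. In every library 13026 genes reached 1 CPM, and 30574 of the 60675 genes had 0 counts in all 4.

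HDAC6 RNA was present at a low level in every library labelled as KDAC6 knockout. HDAC6 (ENSG00000094631, chromosome X, 48801377 to 48824982, plus strand, GRCh38) had 198, 252, 179 and 194 counts in libraries 1 to 4. The exact 95% Poisson intervals of these counts were 171 to 228, 222 to 285, 154 to 207 and 168 to 223. Its level was 4.62, 5.05, 4.25 and 5.56 CPM, with a mean of 4.87 ± 0.563 CPM (SD, n = 4). This placed HDAC6 at the 22.6th percentile of the 13341 protein-coding genes tested. The estimates for HDAC6 were whole numbers in 4 of 4 libraries. Counts summed over a whole gene do not show which exons the reads came from, so they check neither the altered sequence nor the protein.

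Among the 18 lysine deacetylase genes, HDAC6 ranked 16th by mean CPM. HDAC2 and HDAC1, the catalytic subunits of nuclear corepressor complexes, had the highest CPM, at 185 and 112, 38.0-fold and 23.0-fold the HDAC6 level. The class IIa gene HDAC7 followed at 74.1 ± 5.30 CPM, and HDAC3 at 40.3 ± 1.79 CPM. HDAC9, HDAC5 and HDAC4 were at 32.1, 29.5 and 23.7 CPM, HDAC8 was at 13.01 CPM, and HDAC10, the other class IIb member, was at 18.4 CPM. Of the NAD-dependent sirtuins, SIRT1 was highest at 30.0 ± 0.409 CPM, SIRT6, SIRT7, SIRT2 and SIRT5 were between 15.1 and 19.3 CPM, and the mitochondrial SIRT3 was at 10.95 CPM. In all, 15 of the 17 other genes were higher than HDAC6 in 4 of 4 libraries, whereas HDAC11 (2.05 ± 0.473 CPM) and SIRT4 (0.0883 ± 0.0574 CPM) were lower in 4 of 4. The log2 difference from HDAC6 was 5.11 ± 0.27 for HDAC2, 1.10 ± 0.11 for SIRT3 and -1.09 ± 0.17 for HDAC11 (SD, n = 4, exact sign-flip permutation p = 0.13 and adjusted p = 0.13 for each of the 17, the smallest the design allows). CPM does not correct for gene length. The exonic length used here merges the exons of all annotated transcripts, so it can exceed that of any single mRNA. It was 22986 nt for HDAC8 and 10602 nt for HDAC6, and levels per kilobase depend on it. Levels per kilobase of annotated exon without a pseudocount were an alternative chosen after the data were seen. With them every gene stayed on the same side of HDAC6, but the order of the means changed. HDAC1 (log2 difference 5.95 ± 0.19) passed HDAC2 (4.71 ± 0.29), and HDAC3 (4.25 ± 0.19) passed HDAC7 (4.03 ± 0.09). SIRT6 (3.92 ± 0.02) also passed SIRT1 (3.85 ± 0.18), but by less than the SD of SIRT1. HDAC9, 5th by CPM, had a log2 difference of 2.06 ± 0.28 and fell below HDAC5, HDAC10 and all sirtuins but SIRT4. The log2 difference of HDAC8 was 0.31 ± 0.19 and that of HDAC11 -0.27 ± 0.22. With the pseudocount of 0.5, about the size of the HDAC6 value per kilobase, these 2 were 0.15 ± 0.09 and -0.12 ± 0.09.

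**Figure D1:**
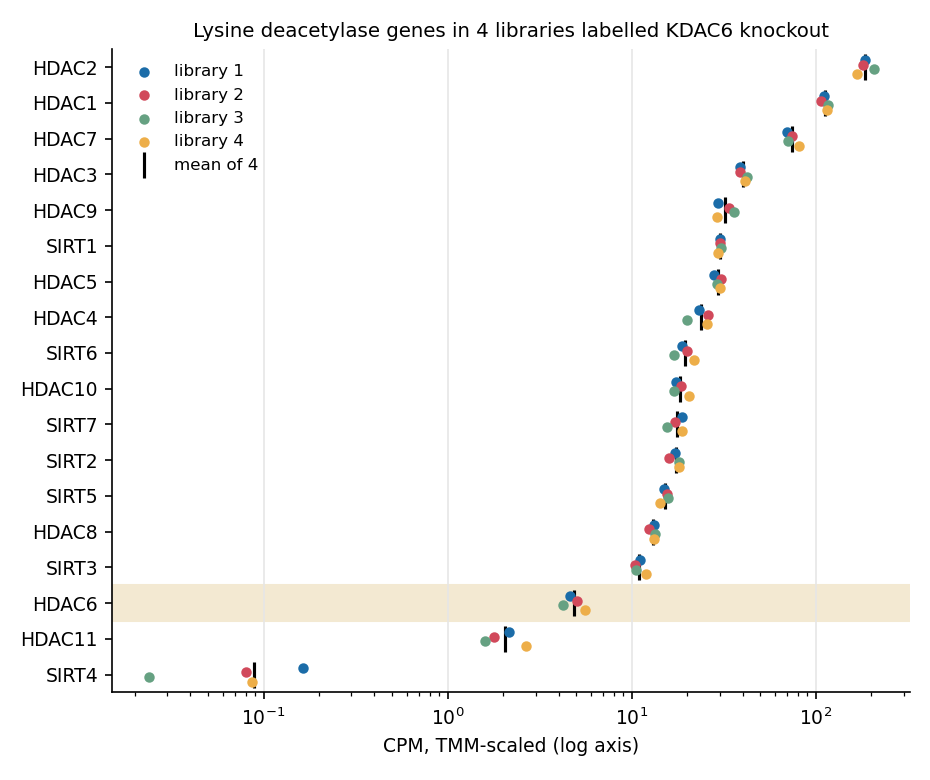
Level of each of 18 lysine deacetylase genes, in TMM-scaled CPM on a log axis, with 1 point per library and a bar at the mean of 4. HDAC6, shaded, has a mean of 4.87 CPM, below 15 of the other 17 genes, from HDAC2 at 185 CPM to SIRT3 at 10.95 CPM.

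Enzymes that add acetyl groups were all expressed: 15 of 15 acetyltransferase genes reached 1 CPM in every library. NAA50, an N-terminal acetyltransferase, was highest at 379 ± 33.0 CPM, followed by KAT6A at 115 ± 2.89, EP300 at 114 ± 8.23 and CREBBP at 98.8 ± 5.08 CPM (SD, n = 4). ATAT1, which acetylates α-tubulin at the lysine that KDAC6 deacetylates, was lowest of the list at 6.45 ± 0.177 CPM. Of the tubulin genes, 9 of 12 were detected, led by TUBB (2262 ± 172 CPM), TUBA1B (2019 ± 191 CPM), TUBA1C (993 CPM) and TUBB4B (695 ± 43.8 CPM). Known substrates and partners of KDAC6 were detected in 20 of 20 cases. The HSP90 genes HSP90AB1 and HSP90AA1 were at 1625 ± 91.0 and 1608 ± 148 CPM, the dynein heavy chain DYNC1H1 at 1001 ± 67.2 CPM and β-catenin (CTNNB1) at 532 ± 7.30 CPM. Tubulin genes and their copies are similar in sequence, so how reads were divided among them is uncertain.

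Most genes of protein quality control, in which KDAC6 is known to act, were also detected. Of the chaperone and heat shock response genes, 14 of 16 were detected, with HSPA8 at 2352 ± 84.9, the mitochondrial chaperonin HSPD1 at 594 ± 32.0, PTGES3 at 403 ± 34.9 and HSPA4 at 326 ± 20.7 CPM (SD, n = 4). Of the aggresome and autophagy genes, 19 of 20 were detected. The ubiquitin-binding cargo receptor SQSTM1 was at 540 CPM, BAG6 at 287 ± 18.3, UBQLN1 at 244 and the lysosomal LAMP1 at 216 ± 15.2 CPM.

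Most mesenchymal and actin cytoskeleton genes were detected. All 20 actin cytoskeleton and migration genes were detected, led by ACTB at 5487 ± 469, ACTG1 at 4123 ± 374, MYH9 at 2185 ± 136 and ACTN4 at 1338 ± 78.5 CPM (SD, n = 4). Of 22 mesenchymal and fibrosarcoma markers, 18 were detected. The intermediate filament gene VIM was at 5055 ± 319 CPM, fibronectin (FN1) at 2030 ± 293, the hyaluronan receptor CD44 at 1453 ± 57.8 and the membrane-bound metalloprotease MMP14 at 1113 ± 148 CPM. Of the fibrillar collagen genes, COL27A1 was at 37.6 ± 5.53 CPM, COL5A1 at 32.3 ± 5.19 and COL1A1 at 3.27 ± 0.421, and COL1A2 (0.037 CPM) and COL3A1 (0.0059 CPM) were close to 0. These 5 were chosen after their values were seen.

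Markers of other cell types were mostly absent or near the floor. Of 12 epithelial markers, 3 were detected: KRT8 at 219 ± 12.3 CPM, KRT18 at 192 ± 9.60 CPM and CLDN4 at 2.58 CPM (SD, n = 4). Of 12 immune markers, only the lysosomal gene CD68 (83.8 ± 7.20 CPM) and CSF1R (2.45 ± 0.494 CPM) were detected, and LYZ was at 0.506 CPM. None of the 8 endothelial markers were detected (0 of 8), with TEK, KDR and PECAM1 at 0.769, 0.389 and 0.103 CPM. Of 12 skeletal muscle and neural markers, SNAP25 was at 8.53 ± 0.923 and MYH3 at 2.53 ± 0.617 CPM, while MBP was at 0.498 CPM and the remaining 9 were lower.

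Cell cycle genes were highly expressed, with 20 of 20 proliferation genes detected. CCND1, which drives entry into S phase, was at 792 ± 16.9 CPM, TOP2A at 675 ± 35.3, MKI67 at 626 ± 26.3 and the replicative helicase subunit MCM7 at 334 ± 13.2 CPM (SD, n = 4). Of the cell cycle arrest and damage response genes, 13 of 14 were detected, including MDM2 at 340 ± 18.6, GDF15 at 237 ± 24.6 and CDKN1A at 143 ± 9.46 CPM. The exception was CDKN2A, the gene for the cell cycle inhibitor p16, with 0 counts in 4 of 4 libraries. That count allows at most 0.0700, 0.0601, 0.0713 and 0.0860 CPM in libraries 1 to 4.

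Median log2 levels of the stress lists differed, though no test compared them. They were 6.08 ± 0.04 for the integrated stress and unfolded protein response and 6.47 ± 0.07 for oxidative stress. All 15 genes of the integrated stress and unfolded protein response were detected, led by the chaperones CALR (800 ± 75.3 CPM) and HSP90B1 (779 ± 65.5 CPM), then ATF4 (419 ± 33.7 CPM) and ASNS (226 ± 18.2 CPM). All 14 oxidative stress genes were detected, with TXNRD1 at 744 ± 33.0, GPX1 at 222 ± 15.9, PRDX3 at 148 ± 12.9 and SOD2 at 119 ± 16.2 CPM (SD, n = 4). Interferon response genes had a low median log2 level of 2.24 ± 0.02, although 18 of 20 were detected and IFITM3 was at 107 ± 8.51 CPM. STAT2 and IRF1 were at 42.4 ± 2.82 and 23.2 ± 0.727 CPM. Immediate early genes, which respond to handling, had a median log2 level of 3.27 ± 0.07. Of these, 12 of 15 were detected, with KLF6 at 210 ± 3.50, JUN at 187 ± 5.37, IER3 at 96.1 ± 7.90 and IER2 at 85.8 ± 5.39 CPM.

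Every member of the 2 metabolic lists, for glycolysis and hypoxia and for cholesterol synthesis, was detected. All 17 glycolysis and hypoxia genes were detected, with GAPDH at 4472 ± 326, PKM at 2965 ± 135, ENO1 at 2764 ± 159 and LDHA at 1840 ± 93.8 CPM (SD, n = 4). All 14 cholesterol synthesis genes were detected, with the transcription factor SREBF2 at 222 ± 14.7 and CYP51A1 at 112 ± 2.77 CPM. The 13 housekeeping genes had the highest median log2 level of any list of nuclear mRNAs, 9.66 ± 0.11, led by EEF1A1 at 10350.3 ± 940 and including RPLP0 at 2000 ± 233 CPM.

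**Figure D2:**
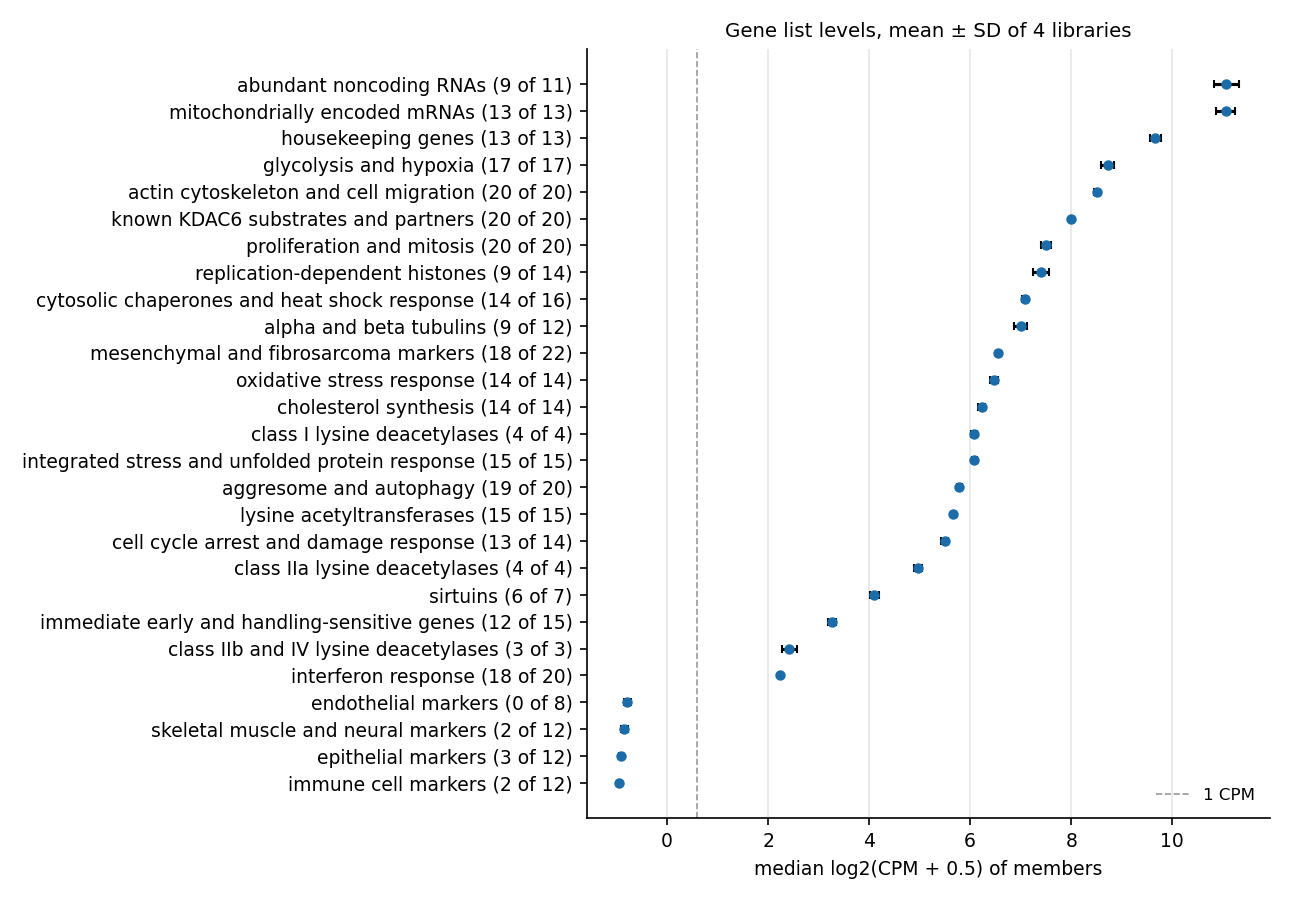
Median log2(CPM + 0.5) of the members of each of 27 gene lists, with points at the mean of 4 libraries, bars of 1 SD, and in parentheses the members that reached 1 CPM in every library. The dashed line marks 1 CPM: the 4 lists of other cell types lie below it, and the other 23 lie above.

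A few short structural RNAs took a large part of the counts. The 7SL RNA of the signal recognition particle (RN7SL1 and RN7SL2) held 4.14% ± 0.931 of all counts (SD, n = 4), and the transcription regulator 7SK (RN7SK) held 2.12% ± 0.432. RPPH1 and RMRP, the RNAs of RNase P and RNase MRP, together held 1.14% ± 0.214. RN7SL1 (24748 ± 5458 CPM), RN7SK (21266 ± 4661 CPM) and RN7SL2 (16810 ± 4634 CPM) were the 3 most abundant genes. EEF1A1, MT-CO1, RPPH1 (7111 ± 917 CPM), ACTB, VIM, GAPDH and RMRP (4320 ± 1529 CPM) completed the 10 most abundant. The 13 mRNAs of the mitochondrial genome held 2.85% ± 0.236 of counts, with MT-CO1 at 7818 ± 92.8, MT-CO3 at 3545 ± 413, MT-ND4 at 3454 ± 368 and MT-CO2 at 2765 ± 259 CPM. Ribosomal protein genes held 5.15% ± 0.277, long noncoding RNAs 1.14% ± 0.108, small nucleolar and Cajal body RNAs 0.117% ± 0.0512, the 14 listed histone genes 0.277% ± 0.0231, and nuclear protein-coding genes 87.9% ± 1.92. Of the histone genes, 9 of 14 were detected, including HIST1H1E at 536 ± 81.0, HIST1H1C at 516, HIST1H2AC at 362 ± 27.5 and HIST1H4C at 341 ± 61.8 CPM. 7SL and 7SK have many copies in the genome, so the counts of their single genes depend on how shared reads were divided.

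The 4 libraries were close to each other but differed by more than counting noise. Pearson correlations of log2 levels across the 17176 genes tested, which are not independent replicates, were between 0.995 and 0.997 for the 6 pairs. The chi-square of the counts per degree of freedom was between 13.4 and 37.1, against the value of 1 that counting noise alone gives. Abundant genes such as RN7SL1 and RN7SK weigh most in this sum over genes, so the excess need not hold for most genes. This excess may be technical and does not show that the replicates came from separate cultures. The common biological coefficient of variation was 9.44%. The median SD of log2 levels was 0.15 for the 4050 genes between 1 and 10 CPM and 0.10 for the 7292 genes between 10 and 100 CPM.

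Genes that vary between replicates depend on the form of the test. In the planned form of the edgeR variance test, with a prior fitted to each gene, 0 of 17176 genes varied (705 at an unadjusted p under 0.05). The planned form also recovered 0% of simulated 4-fold changes. The limma-voom test called 199 genes, but it also used a common prior. DESeq2 flagged 196 dispersion outliers, by a rule that gives no adjusted p-value. Neither is independent evidence against the 0. A form with 1 common prior, chosen after both counts had been seen, called 172 genes, and a fit without a robust prior, set beforehand, called 80, all among the 172. The adjusted p-values for varying genes come from the form chosen later.

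In that form, 7 of the 10 genes with the smallest adjusted p were mitochondrial rRNAs, entries inside 18S rRNA genes or small structural RNAs. MT-RNR1, the mitochondrial 12S rRNA gene (ENSG00000211459, mitochondrial genome, 648 to 1601), was at 82.2, 9.21, 20.2 and 4.27 CPM in libraries 1 to 4 (edgeR quasi-likelihood variance ratio, adjusted p = 6.7e-15). The 16S rRNA gene MT-RNR2 was at 106, 14.9, 30.0 and 6.97 CPM (adjusted p = 6.7e-15). The entries CH507-513H4.4, CH507-513H4.6 and CH507-513H4.3 on chromosome 21, annotated as long noncoding RNAs, lie by position inside the 18S rRNA genes RNA18SN3, RNA18SN2 and RNA18SN1. The entries are on the minus strand, and the strands were not compared. Without a strand setting the origin of their reads is uncertain. All 3 had identical values of 223, 33.0, 76.7 and 20.4 CPM (adjusted p = 6.7e-15), so they are 1 measurement. A second entry of RN7SL1 (ENSG00000283029) at the same position as the first was at 99.0, 28.5, 66.2 and 11.8 CPM (adjusted p = 1.0e-12). The first entry holds far more counts, at 20149 to 32663 CPM, and did not vary when adjusted over all genes (edgeR adjusted p = 0.65). How reads were divided between these entries is uncertain, so the second does not show that 7SL RNA varied as much. The Cajal body RNA SCARNA7 was at 60.0, 20.4, 37.1 and 10.98 CPM (adjusted p = 6.2e-10). These 7 genes were highest in library 1 and lowest in library 4.

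Other leading genes varied in other ways. ITGB1P1, a processed pseudogene of the integrin gene ITGB1, was at 19.1, 7.29, 0.333 and 0.0287 CPM in libraries 1 to 4 (edgeR adjusted p = 6.7e-15). The antisense gene RP11-386G11.10, now TUBA1B-AS1, was at 13.8 CPM in library 1 and at most 0.499 CPM elsewhere (adjusted p = 1.5e-13). RP11-290L1.3, now PHLDA1-AS1, was at 5.07 CPM in library 4, 0.380 and 0.357 CPM in libraries 2 and 3 and 0 counts in library 1 (adjusted p = 1.8e-08). The pseudogene shares sequence with its abundant parent, and the antisense genes cannot be told from their sense partners without strand, so these 3 values are uncertain.

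By the form chosen later, 172 of 17176 genes varied at an adjusted p under 0.05, and 1032 did at an unadjusted p under 0.05. Small noncoding RNAs (16 of 50) and genes of the mitochondrial genome (7 of 15) were over-represented, with odds ratios of 51.1 and 89.9 (Fisher's exact test across genes, adjusted p = 5.5e-20 and 1.1e-10). Long noncoding RNAs (46 of 2392, odds ratio 2.28, adjusted p = 1.6e-05) and pseudogenes (19 of 994, odds ratio 2.04, adjusted p = 0.0074) were too, and nuclear protein-coding genes were under-represented (71 of 13328, odds ratio 0.199, adjusted p = 3.8e-24). Of the 172 genes, 65, 62, 26 and 19 were highest in libraries 1 to 4, and 27, 11, 52 and 82 were lowest there. Among the 80 genes of the fit without a robust prior, small noncoding RNAs (13 of 50, odds ratio 89.1) and mitochondrial genes (5 of 15, odds ratio 113) were over-represented as well (Fisher's exact test across genes, adjusted p = 3.2e-19 and 1.1e-08). Fisher's test treats genes as independent, but many of these RNAs moved together, highest in library 1 and lowest in library 4. Entries with identical values were also counted as separate genes. The Fisher p-values therefore do not measure replication across libraries. By the form chosen later, the count of varying genes was 301 without the count filter and 86 without replicate 4.

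Of the 316 list genes tested, 9 varied by the form chosen later when adjusted over all genes, and 0 in the planned form. They were 5 mitochondrial mRNAs (MT-ND3, MT-ND4L, MT-ND6, MT-ATP6 and MT-ATP8), MT-RNR1, MT-RNR2, RMRP and the nuclear paraspeckle RNA NEAT1. RMRP was at 6445 CPM in library 1 and 2817 CPM in library 4 (edgeR adjusted p = 0.0025), and NEAT1 was highest in library 2, at 462 CPM against 198 to 292 CPM in the other libraries (edgeR adjusted p = 2.1e-05). Adjusted over the list alone, 16 genes varied: 8 abundant noncoding RNAs, 6 mitochondrial mRNAs, the histone gene HIST1H4C and the hypoxia gene CA9. None of the deacetylase, acetyltransferase, tubulin, chaperone, autophagy or KDAC6 partner genes varied under either adjustment (0 genes), and the simulated test missed 13 of 100 genes changed 2-fold in 1 library. Few genes of any kind varied, so this count does not set these lists apart.

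**Figure D3:**
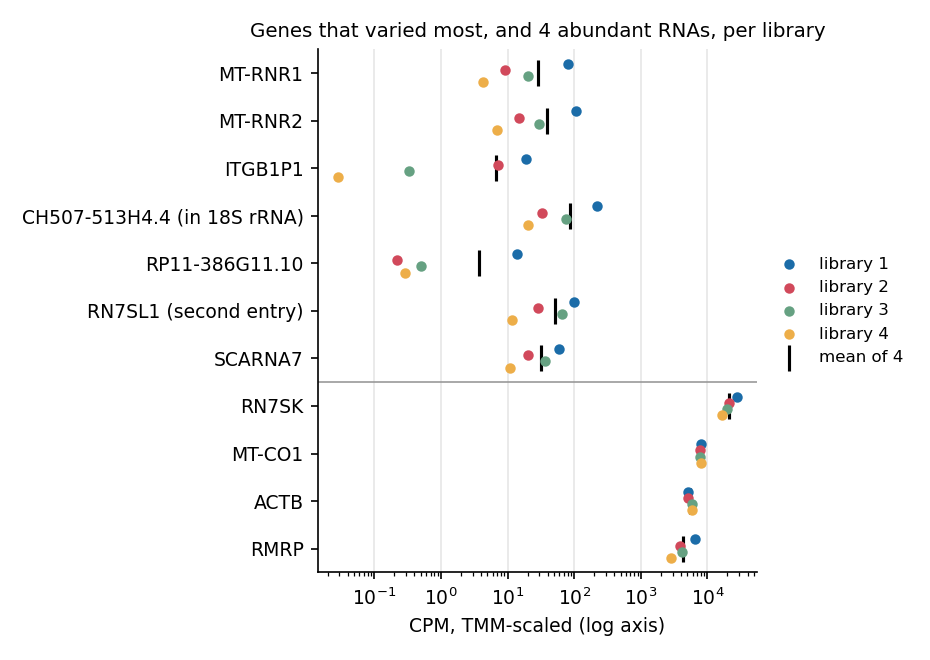
Level of 7 of the genes that varied most (above the line) and of RN7SK, MT-CO1, ACTB and RMRP (below it), in TMM-scaled CPM on a log axis, with 1 point per library and a bar at the mean of 4. MT-RNR1 spans 4.27 to 82.2 CPM across the libraries, whereas MT-CO1 spans 7700 to 7897 CPM.

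As groups, 3 of the 26 lists with enough members spread more between libraries than random lists of the same size and expression. The median SD of log2 levels was 0.36 for the abundant noncoding RNAs, 0.19 for the mitochondrial mRNAs and 0.16 for the histone genes, against 0.10, 0.09 and 0.10 in random lists (permutation p = 0.0002 for each, the smallest the 10000 lists can give, adjusted p = 0.0017). The random lists draw genes independently, whereas members of a list can move together between libraries. These permutation p-values therefore do not measure replication across libraries. Without replicate 1 the mitochondrial mRNAs had an adjusted permutation p of 0.088. The histone result was lost without replicate 2 (adjusted permutation p = 0.61), with plain CPM (0.11), with at least 50 counts in every library (0.15) and with the quasi-dispersion in place of the SD (0.15). KDAC6 substrates and partners were at the 1.82nd percentile (permutation p = 0.037, adjusted p = 0.19) and mesenchymal markers at the 98.5th (permutation p = 0.031, adjusted p = 0.19), and neither passed the adjustment. The other 21 lists had adjusted p-values from 0.30 to 0.90, and the endothelial list had too few members tested.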

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

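All tests of explanations in this part were chosen after the result was seen. Of 152 values compared across the 4 libraries, 9 had 1 library far from the other 3 relative to the whole range. Chance gives about 1 in 20 for independent values. These were not independent: list medians stood beside their own members, and 3 entries had identical values. The 152 also included the 10 genes chosen for the smallest adjusted p for variance, among them RP11-386G11.10, so the rate is only a rough guide. NAA50 was highest in library 3 at 428 CPM, against 356 to 366 CPM in the others. PRDX3 was also highest in library 3, at 167 CPM against 140 to 143 CPM. The median log2 level of the housekeeping genes was highest in library 3, at 9.82 against 9.60 to 9.61. KLF6 was lowest there, at 204 CPM against 211 to 212 CPM, a small gap that passed because the ratio is relative to the range. BAG6 and IER2 were highest in library 4, at 314 CPM against 275 to 281 CPM and at 93.8 CPM against 82.6 to 83.4 CPM. SOD2 was highest in library 2, at 143 CPM against 109 to 112 CPM. RN7SL2, at 23679 CPM, and the antisense gene RP11-386G11.10, at 13.8 CPM, were highest in library 1. In the variance test chosen later, NAA50, PRDX3, KLF6, BAG6, IER2 and SOD2 did not vary (edgeR adjusted p of 0.63 or more). Adjusted over all genes, RN7SL2 did not vary either (edgeR adjusted p = 0.20).

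MT-RNR1, MT-RNR2 and CH507-513H4.4, the entry that lies by position inside an 18S rRNA gene, were highest in library 1 and lowest in library 4. So were many short structural RNAs, though RPPH1 (6184 CPM) and SNORD3A (436 CPM) were lowest in library 3. Whether uneven removal of rRNA is the whole cause was asked of 17 small nucleolar and Cajal body RNAs. They differed by 1.19 relative to nuclear protein-coding genes (95% bootstrap interval over genes 1.05 to 1.45), so rRNA was not all that moved. Short RNAs were part of the pattern when this test was chosen, so it gives no independent evidence on the cause. For the rRNA part uneven retention of short RNAs cannot be told apart from other causes. The median log2 difference of MT-RNR1, MT-RNR2 and CH507-513H4.4 was 3.83, against 2.34 at a high percentile of 44 noncoding RNAs of at most 400 nt. These 3 genes were picked for showing the pattern. They are annotated at 954, 1559 and 923 nt, longer than those noncoding RNAs, but the lengths of the RNAs sequenced are not known here. For the small RNA part uneven retention stays open too: 52 short mRNAs of at most 600 nt differed by 0.11, with an interval of -0.01 to 0.23 that includes 0. Mitochondrial mRNAs as a list moved the same way, with a median log2 difference of 0.46 relative to nuclear protein-coding genes. Not all did: MT-CO1 (1542 nt) was at 7888 CPM in library 1 and 7897 CPM in library 4. The shift was large for MT-ATP8 (207 nt, 54.1 against 22.5 CPM) and MT-ND4L (297 nt, 332 against 94.5 CPM). It was smaller for MT-CO2 (684 nt, 2989 against 2491 CPM) and MT-CO3 (784 nt, 4085 against 3214 CPM). A relation to length over all these mRNAs was not tested. A mixture of uneven rRNA removal and uneven retention of short RNAs may apply. No biological explanation was tested because the libraries form 1 group.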

How the results depend on the processing

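Chosen after seeing the data were the common prior of the variance test, which gave the 172 genes, the coding-only variance test, levels per kilobase without a pseudocount and other scalings for libraries that stand apart; all others were planned. No paired analysis was possible because the labels give only 1 group. A change of direction was checked only for the lysine deacetylase differences from HDAC6 and the 3 lists that spread more. None of these changed direction. With a total that leaves out mitochondrial and abundant noncoding RNA, HDAC6 was at 5.45 CPM, and the shares became 5.76% for ribosomal protein genes, 0.31% for histones, 1.28% for long noncoding RNAs and 98.2% for nuclear protein-coding genes, as the smaller denominator requires. The planned form of the variance test, with each gene's own prior, gave 0 varying genes in place of 172, because that prior weakens for the genes that vary most. The 172 became 301 without a count filter, all 172 among them, 80 without the robust prior, all of them among the 172, and 87 when only nuclear protein-coding genes were tested, of which 71 were among the 172; the cause was not tested. Leaving out each replicate gave from 86 (without replicate 4) to 174 (without replicate 1), of which 85 and 120 were among the 172. Plain CPM gave 244, DESeq2 size factors 174, at least 50 counts 122, limma-voom 199 and DESeq2 dispersion outliers 196. The remaining 97 values of the main results stayed within their spread or within 1.5 times, including HDAC6 at 4.62 to 5.10 CPM without each replicate. Among single genes and lists, 41 values moved beyond their spread, mostly levels per kilobase, 5 list calls were lost and 3 were gained. With plain CPM the KDAC6 substrates and partners passed (adjusted p = 0.043), as did actin genes without replicate 3 (0.045) and mesenchymal markers with at least 50 counts (0.030). Depth limits SIRT4, with 1 to 7 counts per library, and markers near the floor.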

Other observations

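The gene families, gene pairs, chromosome differences and long noncoding RNA pattern here were chosen after the values were seen, as were the tests of transcript length and chromosome number. The tests of genomic DNA and GC content were set before their results, but after the patterns they explain had been seen. Of 26 integrin subunit genes, 17 were detected, led by ITGB1 at 2118 ± 126 CPM, ITGA3 at 1451 ± 156 CPM and ITGA2 at 749 ± 63.7 CPM (SD, n = 4). Of 44 collagen genes, 18 were detected, and COL6A3, at 3722 ± 374 CPM, was far above its partner chains COL6A1 (159 ± 21.7 CPM) and COL6A2 (147 ± 22.9 CPM). Basement membrane genes included COL4A2 at 358 ± 62.4 CPM and the laminin chains LAMC1 and LAMB3 at 647 ± 40.1 and 573 ± 42.8 CPM. The caveolar genes CAV1 and PTRF were at 558 ± 31.4 and 349 ± 27.4 CPM. CPM is not corrected for transcript length.

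The most abundant of 55 keratin genes was KRT81, a hair keratin, at 1068 ± 73.9 CPM (SD, n = 4), above KRT8 and KRT18, while 9 of the 55 were detected. Germline antigen genes of the MAGE-A family were expressed, with 7 of 12 detected, MAGEA6 at 105 ± 4.17 CPM and MAGEA3 at 97.4 ± 5.83 CPM, though the division of reads between these similar copies is uncertain. In iron handling, the transferrin receptor gene TFRC was at 1026 ± 58.4 CPM and the ferritin genes FTL and FTH1 at 830 ± 130 and 639 ± 86.5 CPM. Of 13 HLA class II genes, 2 were detected, HLA-DPA1 at 4.67 ± 0.213 CPM and HLA-DPB1 at 4.05 ± 0.431 CPM.

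Some near-identical genes varied more singly than as a pair; varying here means by the variance test form chosen after the planned form gave 0 genes. RGPD5 was at 51.8, 47.4, 32.0 and 26.7 CPM in libraries 1 to 4 while RGPD6 was at 17.1, 24.9, 35.7 and 40.7 CPM, and both were among the 172 varying genes. The coefficient of variation was 30.5% for RGPD5 and 35.9% for RGPD6, and 3.24% for their sum. SULT1A3 and SULT1A4 had coefficients of 65.5% and 56.4%, and their sum 7.81%. MAGED4 and MAGED4B had 53.05% and 41.1%, and their sum 12.3%. For EIF3CL it was 41.0%, and 6.23% for its sum with EIF3C, which EIF3C dominates (1043 against 23.6 CPM), so this pair does not show the same.

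Of 144 long noncoding RNAs with a mean of 10 CPM or more, 35.4% were highest in library 2. Of protein-coding genes at that level it was 13.4%, a difference that was not tested. The median deviation of these long noncoding RNAs in library 2 was only 0.04 on the log2 scale. Genomic DNA in library 2 is argued against by 375 olfactory receptor genes, whose excess there was -0.00029 CPM per kb (upper bound 0.00053), against the 0.158 CPM per kb that the pattern needs. Protein-coding genes in library 2 deviated with transcript length (Spearman's rho 0.55 across genes, which are not independent replicates). A length trend as the whole cause is argued against, since long noncoding RNAs exceeded protein-coding genes of matched length by 0.0756 (95% bootstrap interval 0.0547 to 0.0928). Annotated lengths of long noncoding RNAs can be incomplete, and no biological explanation was tested.

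Genes of some chromosomes had higher levels in library 4 than in library 3, with chromosome medians from -0.11 to 0.13 on the log2 scale over 10515 protein-coding genes. A candidate explanation is a trend with GC content: removing it reduced the SD across chromosomes to 0.157 of its value, from 0.068 to 0.011. Genes above 55.7% GC differed by 0.19 and those below 41.6% by -0.16, with a Spearman's rho of 0.70 across genes. A difference in chromosome number is argued against, since the largest median left was 0.0288, on chromosome 21 (95% bootstrap interval -0.0288 to 0.0760), and no chromosome's interval went beyond 0.0760 in size. What produced the GC trend stays open, and no biological explanation was tested.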
